A study of Mus musculus with 2 samples.

How the data were processed

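Trimethylation of lysine 27 of histone H3 (H3K27me3), the mark that Polycomb repressive complexes place at silent genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in midbrain dissected from mouse embryos at day 11.5 of gestation. Per the labels, the tissue came from strain B6NCrl, each biological replicate was a pool of embryos of both sexes, replicate 1 held 109 embryos and replicate 2 held 88, and DNA of 300 to 500 bp was selected. The labels give 1 group of 2 biological replicates, each with 2 technical replicates combined, and no second condition. The comparisons were therefore the agreement of the 2 replicates and the placement of the mark along the genome.

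The authors deposited 4 peak lists, all on mm10 per the read-me files of the samples. One list was called for each biological replicate, one was called on both replicates together (the pooled list), and one holds replicated peaks derived from the other 3. Each call used filtered alignments and the same 2 control files, per the read-me files. The aligner, the peak caller, their versions, the thresholds and the rule that makes a peak replicated are not given in the sources used here. All 30245 rows of the replicated list were rows of the pooled list, and 19862 of them overlapped a peak of both replicates. The deposited values per peak were a signal value, the −log10 of a p-value and the −log10 of a q-value, all set by the authors' peak caller. The lowest −log10 p-value in the deposited lists was 2.00, and the signal and the −log10 p-value were used only to rank or filter peaks within a list. The files carry no read counts, so the depth of each replicate is unknown and no interval for read counts could be given. A longer list can come from deeper sequencing or from a stronger enrichment, and peak counts were not read as amounts of the mark. Alignments and signal tracks were not analysed here.

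Gene models came from GENCODE release M21 and the sequence from the RefSeq copy of GRCm38, the assembly that mm10 names. Of 20660 gene names shared by GENCODE and RefSeq, 20656 overlapped on the same strand. Peaks were compared with 21938 protein-coding genes on chromosomes 1 to 19, X and Y. A gene was called marked when a peak covered at least 1 bp of the window of 1 kb on either side of its annotated start. The covered length was also measured in the 5 kb on either side of the start, a window of 10 kb, and is given as the mean of the 2 replicates ± SD. Promoters were called CpG-rich when the 500 bp on either side of the start had an observed over expected CpG ratio of at least 0.6 and a GC content of at least 50%. Peaks at most 3 kb apart were joined into domains, and domains of at least 10 kb were called long. Positions are 1-based.

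The gene lists, the tests and the alternatives were fixed before the data were examined. Each of 22 gene lists was compared with all other protein-coding genes by a two-sided Fisher's exact test on the replicated list, with Benjamini-Hochberg adjustment over the 22 lists and a threshold of 0.05. These p-values describe genes in this tissue and not the spread between animals, and neighbouring genes such as the Hox clusters share domains and are not independent. A comparison of 14 of the lists with each other, 91 pairs with members of both lists left out, was added after their counts were seen. Overlap between replicates was set against 1000 random placements of the peaks within their chromosomes (200 for the alternatives), with smallest possible p-values of 0.001 and 0.005. CpG content was tested with 100000 resamples of the genes. On data simulated over the 21938 genes, the list test called 50 of 50 lists of 25 genes marked at 80% and 6 of 1000 lists marked at the background of 15%, and returned a mean share of 79.1% for the former. The simulated genes were marked independently and the lists were drawn at random. These rates therefore do not cover neighbouring genes that share domains, smaller lists or lists marked at shares between 15% and 80%.

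The genes named followed a rule set in advance. It took the 3 members of each list with the most bases around the start covered by replicated peaks and the first 2 unmarked members by name. For lists with fewer than 50% of members marked, it took up to 6 marked members. It also took up to 6 genes starting in each of the 10 longest domains, in genome order, and the 10 genes outside every list with the most bases so covered. Not every gene that the rule took is named below, and some of the unmarked genes left out were marked in replicate 2. Names outside the rule are stated as such.

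The alternatives were each replicate alone, the pooled list, peaks with a p-value of 1e-05 or below, windows of 2.5 kb and 500 bp, a window at least 50% covered, any annotated transcript start, CpG-rich promoters only, joining gaps of 1 and 10 kb, and for the overlap a 50% minimum or equal numbers of peaks. Autosomal genes only, replicated peaks that overlap both replicates, and alternatives for the chromosome distribution were added after the data were seen. The work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.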

Results

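H3K27me3 was profiled in the midbrain of mouse embryos at day 11.5, when the neural tube holds dividing progenitors and the first neurons. The group had 2 biological replicates, pools of 109 and 88 embryos of mixed sex. Replicate 1 had 34300 peaks over 16.4 Mb with a median length of 268 bp, and replicate 2 had 89397 peaks over 42.1 Mb with a median length of 263 bp. The list called on both replicates together had 35188 peaks over 22.4 Mb, and 30245 of these, over 21.3 Mb and with a median length of 351 bp, formed the authors' list of replicated peaks. The replicated list is the basis of the values below unless a replicate is named, and the depth behind each list is unknown.

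The first question was which genes carried the mark. Hox genes, which set position along the trunk and hindbrain and are silent in midbrain, were marked in 39 of 39 cases, and on average 9.64 ± 0.196 kb (SD, n = 2) of the 10 kb around their starts lay in peaks. All 25 regulators of hindbrain and spinal cord were marked, among them the motor neuron factor Mnx1 with 9.66 ± 0.356 kb (SD, n = 2) and Olig2 with 9.75 ± 0.349 kb. Forebrain regional factors were marked in 26 of 28 cases, among them Six3 (9.84 ± 0.137 kb), Fezf2 (9.78 ± 0.258 kb) and Vax1 (9.53 ± 0.324 kb), with Hesx1 and Bcl11b unmarked. Factors of other germ layers were marked as well: 30 of 35 for mesoderm and muscle, with Hand1 at 9.66 ± 0.274 kb and Wt1 at 9.62 ± 0.265 kb, and 14 of 18 for endoderm, with Cdx2 at 9.89 ± 0.0905 kb and Foxf1 at 9.86 ± 0.132 kb. Among neural crest and mesenchyme genes 15 of 18 were marked, including Tfap2a (9.62 ± 0.308 kb), Alx4 (9.40 ± 0.563 kb) and Pdgfra (8.91 ± 0.964 kb), while the collagen gene Col3a1 and Dcn had no peak in the 10 kb window in either replicate. The genes named here with a covered length were among the most covered of their lists, and the list means were lower. These means were 7.94 ± 0.779 kb (SD, n = 2) for hindbrain and spinal cord, 7.78 ± 0.856 kb for forebrain and 6.17 ± 0.786 kb for mesoderm and muscle. For endoderm the mean was 5.74 ± 0.835 kb and for neural crest and mesenchyme 4.80 ± 0.980 kb. In all, 3427 of 21938 protein-coding genes (15.6%) were marked. Relative to all other genes the marked share was 6.46 times as high for Hox genes (adjusted p = 3.29e-31), 6.44 times for hindbrain and spinal cord factors (4.74e-20), 5.98 times for forebrain factors (1.01e-18), 5.53 times for mesoderm and muscle factors (3.69e-19), 5.35 times for neural crest and mesenchyme genes (1.10e-09) and 4.995 times for endoderm factors (2.01e-08, two-sided Fisher's exact tests). Replicate 2 alone marked 5318 genes and replicate 1 alone 3294, so that the ratios of these 6 lists ran from 3.44 (neural crest and endoderm) through 3.84 (forebrain) and 4.14 (hindbrain and spinal cord) to 4.15 (Hox) in replicate 2 and from 5.20 to 6.73 in replicate 1. When at least 50% of the window had to be covered, they ran from 8.21 (neural crest) to 13.7 (Hox).

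Regulators of the midbrain itself and of the isthmus, the signalling border to the hindbrain, were marked in 27 of 29 cases, 6.00 times the share of other genes (adjusted p = 2.52e-19, Fisher's exact test) and 4.00 times in replicate 2 alone. Gata2, a determinant of midbrain GABAergic neurons, had 9.73 ± 0.122 kb (SD, n = 2) in peaks. Lmx1b, which acts in the isthmus and in dopaminergic progenitors, had 9.37 ± 0.795 kb, and the isthmus gene Pax5 had 9.27 ± 0.607 kb. The 2 unmarked members were Otx2, which specifies forebrain and midbrain, and Meis2. Around the start of Otx2, on chromosome 14 at position 48673819, replicate 1 had no peak bases and replicate 2 had 0.780 kb, and replicate 2 and the pooled list called it marked. Around Meis2 the mean was 1.41 ± 1.45 kb. The list's mean covered length was 7.002 ± 1.09 kb (n = 2). Its marked share did not differ detectably from that of Hox genes (adjusted p = 0.280, Fisher's exact test over 91 pairs of lists) and was above that of neural progenitor genes (adjusted p = 2.31e-04, and 0.0185 in replicate 2 alone). The comparison with Hox genes had little room to show a difference, since both shares lay near the top of the scale. The mean covered length of Hox genes was 9.64 ± 0.196 kb.

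Genes of neural progenitors and young neurons were marked in fewer than 50% of cases in the replicated list and in replicate 1, and in more than 50% in replicate 2. Among 25 progenitor genes 10 were marked (10 in replicate 1 and 16 in replicate 2), 2.57 times the share of other genes (adjusted p = 0.00426, Fisher's exact test), with a mean of 2.43 ± 0.858 kb (SD, n = 2) in peaks. The marked members included Pax6 (9.62 ± 0.484 kb), the proneural factors Neurog1 (8.94 ± 1.33 kb) and Neurog2 (8.07 ± 0.626 kb), and Zic1 (6.91 ± 1.90 kb), whereas the cadherin gene Cdh2 had no peak bases in either replicate. Ascl1 was unmarked in replicate 1 and in the replicated list and marked in replicate 2. Of 23 early neuron genes 10 were marked, and 11 in replicate 1 and 15 in replicate 2 (2.79 times for the replicated list, adjusted exact p = 0.00215), with a list mean of 2.21 ± 0.922 kb in peaks. They were led by Ebf2 (7.41 ± 2.22 kb), Ebf3 (6.89 ± 1.35 kb) and the zinc finger factor Insm1 (5.07 ± 2.02 kb). Ebf1 (5.07 ± 2.27 kb) was marked in replicate 2 and unmarked in replicate 1. Elavl4, an RNA-binding protein of neurons, had no peak bases in either replicate. Dcx, also unmarked in the replicated list, had none in replicate 1 and 0.951 kb in replicate 2, which marked it. Transmitter phenotype genes were marked in 11 of 18 cases (3.92 times, adjusted exact p = 2.90e-05), with a list mean of 3.44 ± 0.768 kb in peaks. These included the glycine transporter Slc6a5 with 9.03 ± 1.15 kb, the vesicular GABA transporter Slc32a1 with 8.51 ± 0.873 kb and Gad2, which makes GABA, with 8.23 ± 1.49 kb, while Ddc had no peak bases. Dbh, unmarked in the replicated list, was marked in replicate 2 with 0.347 kb. When at least 50% of the window had to be covered, neither progenitor genes (ratio 2.14, adjusted exact p = 0.146) nor early neuron genes (2.33, adjusted p = 0.126) passed the threshold.

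All 19 Wnt ligands were marked, and 18 in replicate 2 (6.43 times the share of other genes, adjusted p = 1.44e-15, Fisher's exact test, and 3.92 times in replicate 2), with Wnt10a at 9.02 ± 0.880 kb (SD, n = 2) and Wnt10b at 8.85 ± 0.979 kb. Bmp and Gdf ligands were marked in 14 of 23 cases (3.91 times, adjusted exact p = 2.22e-06), led by Gdf7 (8.40 ± 1.09 kb) and Bmp7 (8.22 ± 0.977 kb), and Fgf ligands in 11 of 22 (3.21 times, adjusted p = 3.20e-04). Fgf8, the signal of the isthmus, had the longest coverage of its family at 9.25 ± 0.487 kb. Replicate 2 marked 15 of the Bmp and Gdf and 15 of the Fgf ligands. The marked share of Wnt ligands was above that of Fgf ligands (adjusted p = 0.00107) and of Bmp and Gdf ligands (adjusted p = 0.00640, Fisher's exact tests over 91 pairs) in the replicated list, and in replicate 2 alone neither difference passed (adjusted p = 0.113 and 0.0793). Fgf and Bmp and Gdf ligands did not differ detectably (adjusted exact p = 0.631). Mean covered lengths of the lists were below those of the ligands named. They were 5.63 ± 1.24 kb for Wnt, 2.51 ± 0.759 kb for Bmp and Gdf and 2.28 ± 0.736 kb for Fgf ligands. Imprinted genes were marked in 12 of 27 cases (2.85 times, adjusted exact p = 6.07e-04), among them Dio3 (8.25 ± 0.398 kb), Dlk1 (8.13 ± 1.58 kb) and Zdbf2 (6.67 ± 2.24 kb). The mean of the imprinted list was 2.09 ± 0.548 kb. Within CpG-rich promoters the imprinted list no longer passed (1.88 times, adjusted exact p = 0.187). That class held 13 of the 27 members, 5 of them marked, and the loss in so small a list does not show that CpG content accounts for the enrichment.

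Olfactory receptor, cell cycle and ribosomal protein genes were marked less often than other genes. None of 1135 olfactory receptor genes was marked (adjusted p = 2.61e-85, Fisher's exact test), and 1 and 2 of them were marked in replicates 1 and 2 alone. None of 24 cell cycle genes was marked (adjusted exact p = 0.0338), among them the mitotic kinase genes Aurka and Aurkb with no peak bases in either replicate. Of 35 ribosomal protein genes only Rpl3 was marked (0.183 times the share of other genes, adjusted exact p = 0.0442), with 2.36 ± 1.26 kb (SD, n = 2). The cell cycle and ribosomal lists no longer passed in replicate 1 alone (adjusted exact p = 0.0518 and 0.0652). Tissue-restricted effector genes were marked in 2 of 24 cases, the muscle genes Acta1 (4.36 ± 1.21 kb) and Ckm (3.73 ± 0.381 kb), and germline and pluripotency genes in 1 of 18, Pou5f1 (3.13 ± 2.06 kb). Replicate 2 marked 5 effector and 4 germline genes (0.859 and 0.917 times), and replicate 1 marked 3 and 2 (0.832 and 0.740 times). Neither list passed the threshold (0.533 times, adjusted exact p = 0.570, and 0.355 times, adjusted p = 0.375). Polycomb complex genes were marked in 6 of 29 cases, 5 in replicate 1 and 10 in replicate 2 (1.33 times for the replicated list, adjusted exact p = 0.463), with Cbx4 at 7.45 ± 0.869 kb and Bmi1 at 4.33 ± 1.94 kb. Bmi1 was marked in replicate 2 and unmarked in replicate 1. The mean of the Polycomb list was 1.10 ± 0.475 kb.

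Among endothelial, blood and microglia genes, markers of cells that enter the neural tube with its vessels, 7 of 22 were marked (2.04 times the share of other genes, adjusted p = 0.0837, Fisher's exact test). The blood factor Tal1 had 9.13 ± 0.906 kb (SD, n = 2), Fli1 7.70 ± 1.53 kb and Sox18 5.16 ± 0.659 kb, while Cdh5 and Aif1 had no peak bases. The mean of this list was 1.58 ± 0.445 kb. The list passed the threshold in replicate 1 alone (2.43 times, adjusted exact p = 0.0157) and did not in replicate 2 alone (1.501 times, adjusted p = 0.233). Of 7 cyclin-dependent kinase inhibitors only Cdkn2a (8.64 ± 0.494 kb) and Cdkn2b (6.13 ± 1.22 kb), the Ink4 pair on chromosome 4, were marked in the replicated list, and replicate 2 alone marked 4. That list did not pass (1.83 times, adjusted exact p = 0.348, and 2.36 times, adjusted p = 0.0779, in replicate 2) unless the window was widened to 2.5 kb (3.06 times, adjusted p = 0.0320) or any transcript start was taken (3.12 times, adjusted p = 0.0319).

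**Figure D1:**
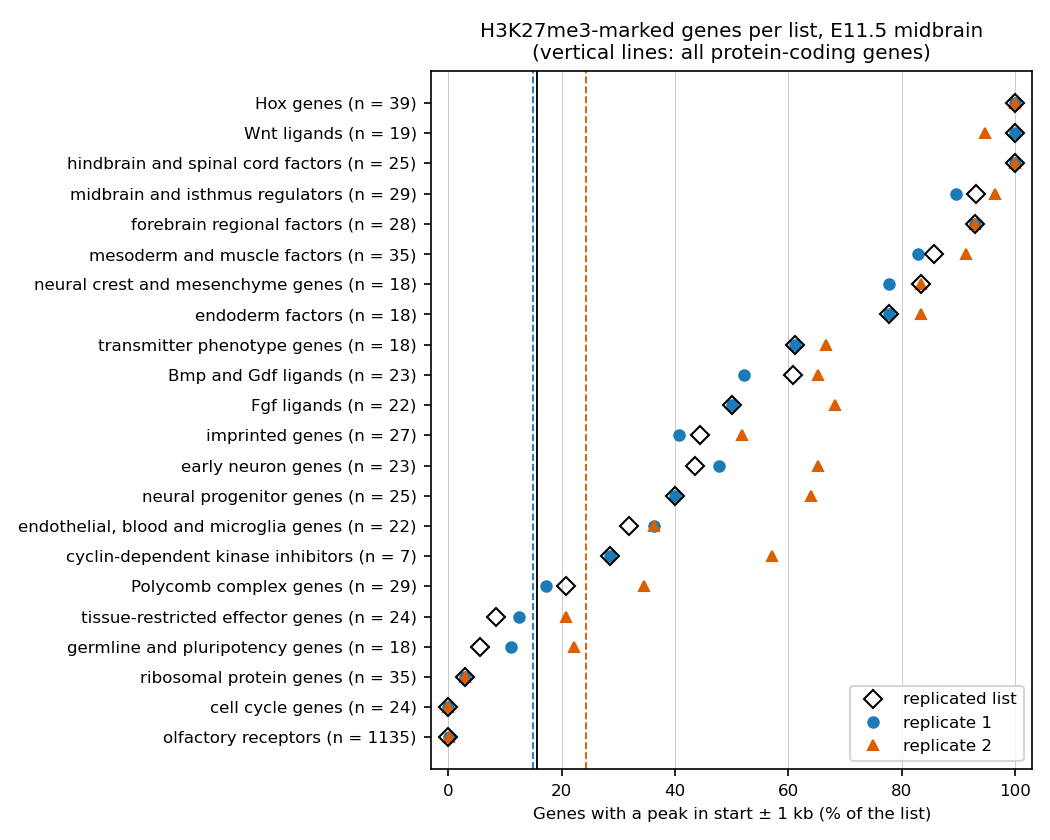
Share of each gene list, in percent of its members (horizontal axis), with a peak within 1 kb of the annotated start, for the replicated list (open diamonds), replicate 1 (circles) and replicate 2 (triangles); vertical lines, dashed for the replicates, give the share of all protein-coding genes (15.6% for the replicated list and 24.2% for replicate 2). Hox genes and hindbrain and spinal cord factors sit at 100% in all 3 lists of peaks, and cell cycle genes sit at 0%.

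Outside the fixed lists, the 10 genes with the most bases covered by replicated peaks were largely homeobox and forkhead factors, a grouping that was not tested against other genes. The homeobox genes Tlx1 (9.95 ± 0.0721 kb, SD, n = 2), Hmx1 (9.94 ± 0.0898 kb), Nkx1-1 (9.72 ± 0.321 kb), Hmx2 (9.72 ± 0.134 kb) and Vax2 (9.62 ± 0.349 kb) and the forkhead genes Foxf2 (9.82 ± 0.144 kb) and Foxd2 (9.54 ± 0.565 kb) were almost wholly covered. The remaining 3 were Gm28308, a gene model inside the HoxA cluster, Insl3, a peptide hormone of the testis, and Gfy. All 10 were marked in both replicates. By the mean of the replicates, Onecut3 (9.895 kb), 5730596B20Rik (9.81 kb), a further gene model inside the HoxA cluster, and Skor1 (9.77 kb) took the places of Gfy, Vax2 and Foxd2, and Onecut3 and Skor1 were named after their values were seen.

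The longest stretches of the mark were the 4 Hox clusters. After joining, 9478 domains remained, and the longest ran over HoxC on chromosome 15 from 102903188 to 103071362 (168 kb), from Hoxc13 to beyond Hoxc4, with 154 ± 7.79 kb (SD, n = 2) in peaks. It was followed by HoxA on chromosome 6 from 52146411 to 52279205 (133 kb, 127 ± 4.10 kb in peaks), HoxB on chromosome 11 from 96247196 to 96377203 (130.0 kb, 124 ± 3.98 kb) and HoxD with Evx2 on chromosome 2 from 74643686 to 74766530 (123 kb, 113 ± 5.06 kb). Next came domains at Pax3, a dorsal neural tube and neural crest factor (chromosome 1, 78135509 to 78221757, 86.2 kb), at Lmx1b (chromosome 2, 33566941 to 33649934, 83.0 kb), at Nfix (chromosome 8, 84732676 to 84815227, 82.6 kb) and at the Zic1 and Zic4 pair (chromosome 9, 91344990 to 91422705, 77.7 kb). The 10 longest also held 2 domains without a protein-coding start, one inside the gene body of Prdm16 on chromosome 4 (154447014 to 154523360, 76.3 kb) and one over the 3′ part of Slc16a2 on X (103678152 to 103763518, 85.4 kb). Long domains numbered 712 and held 46.8% of the peak bases, and 344 of them (48.3%) contained a protein-coding start. Their number was 594 in replicate 1, 1758 in replicate 2, 386 with a joining gap of 1 kb and 1172 with one of 10 kb. The Hox clusters ranked first in replicate 1, whereas in replicate 2 and with the 10 kb gap the longest domain lay on X around Pja1 (495 and 519 kb). With the 10 kb gap the 4 longest domains all lay on X. In replicate 2 those at ranks 1, 2 and 4 lay on X, and HoxC was at rank 3. Hoxc4, Prdm16, Slc16a2 and Pja1 were named after their values were seen.

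**Figure D2:**
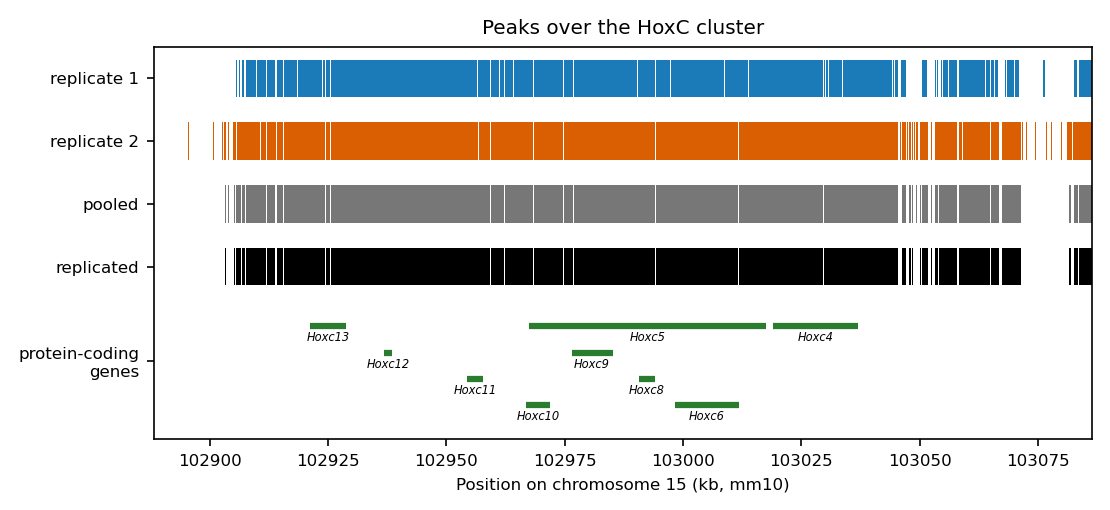
Peaks of replicate 1, replicate 2, the pooled list and the replicated list (bars, from top) and protein-coding gene bodies (green lines) over the HoxC cluster, with the position on chromosome 15 in kb (mm10) on the horizontal axis. Replicated peaks cover 158 kb of the 168 kb domain, 149 kb in replicate 1 and 159.5 kb in replicate 2.

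The mark was enriched at promoters and was more frequent at CpG-rich ones. Windows of 1 kb on either side of protein-coding starts made up 1.56% of the genome and 16.2% of the replicated peak bases, a ratio of 10.4 (10.5 in replicate 1 and 7.42 in replicate 2). Exons held 2.80 times their share of the genome, introns 1.02 times and intergenic sequence 0.559 times. CpG-rich promoters were marked in 20.5% of 9738 cases and other promoters in 11.7% of 12200. The shares were 19.5% and 11.5% in replicate 1 and 29.8% and 19.8% in replicate 2. The observed over expected CpG ratio averaged 0.627 (SD 0.200 over 3427 genes) in marked and 0.489 (SD 0.305 over 18511 genes) in unmarked promoters, a difference of 0.139 (two-sided permutation test over genes, p = 1e-05, the smallest that 100000 resamples can give). Genes are not independent replicates in this test.

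The next question was how far the 2 replicates agreed. Of the genes marked in replicate 1, 95.7% were also marked in replicate 2, which left 141 genes marked in replicate 1 alone, 2165 in replicate 2 alone and 3153 in both. Among peaks, 80.5% of those of replicate 1 overlapped a peak of replicate 2 by at least 1 bp, against 3.20% for random placements, and 21.9% of those of replicate 2 overlapped replicate 1, against 1.21% (one-sided permutation tests, p = 0.001 each, the smallest that 1000 placements can give). The overlap rose with the strength of the peak. In replicate 1 it went from 65.1% in the weakest 25% of peaks by −log10 p to 98.4% in the strongest 25%, and in replicate 2 from 6.64% to 56.0%. With the 34300 strongest peaks of replicate 2, 68.1% of replicate 1 peaks and 42.7% of replicate 2 peaks overlapped. The shared bases, 14.0 Mb, were 85.5% of replicate 1 and 33.3% of replicate 2.

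Peaks covered more of the X chromosome than of the median autosome, in a mixed-sex tissue in which part of the cells carry an inactive X, and the difference was smaller with stricter peaks. Replicated peaks covered 10.9 kb per Mb of X, 1.38 times the median of the 19 autosomes (7.85 kb per Mb), which ranged from 4.82 on chromosome 3 to 16.8 on chromosome 19. The ratio was 1.28 in replicate 1 (7.82 against 6.12 kb per Mb) and 2.13 in replicate 2 (33.4 against 15.7), where X lay above the highest autosome (29.0 kb per Mb). Promoters did not follow: 14.3% of 948 protein-coding genes on X were marked against 15.8% of autosomal genes, and 14.2% against 15.2% in replicate 1, whereas in replicate 2 the shares were 28.9% against 24.2%. No list had a peak on Y. With peaks of a p-value of 1e-05 or below, the ratio of X to the autosomal median was 1.02 in the replicated list, 1.07 in replicate 1 and 1.73 in replicate 2.

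**Figure D3:**
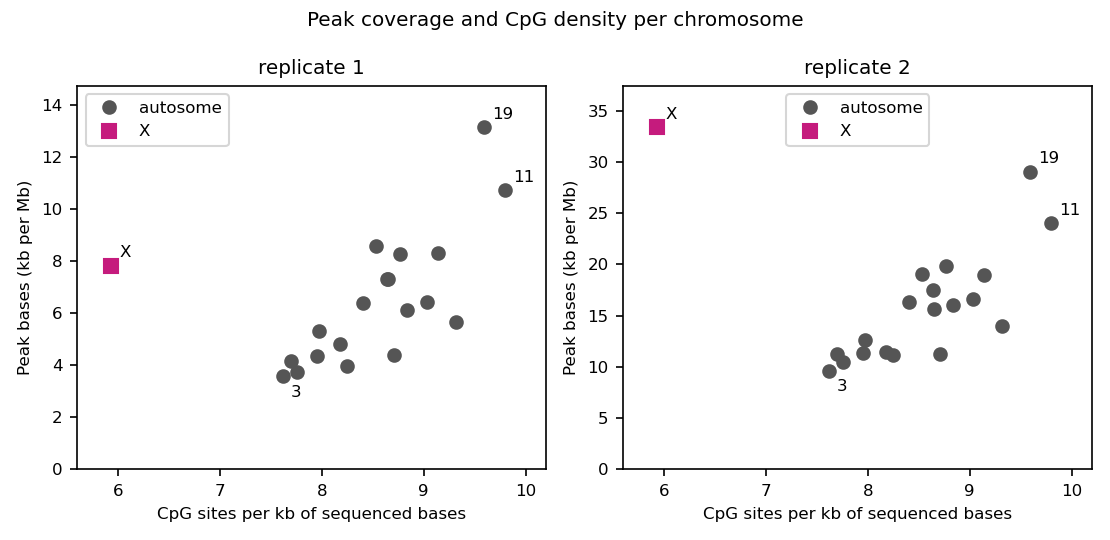
Peak bases in kb per Mb of sequenced bases (vertical axes) against CpG sites per kb (horizontal axes) for each autosome (circles) and X (square) in replicate 1 (left) and replicate 2 (right). X has the fewest CpG sites, 5.93 per kb, and lies at 7.82 kb per Mb in replicate 1 and 33.4 kb per Mb in replicate 2, while the autosomes range from 3.57 (chromosome 3) to 13.2 kb per Mb (chromosome 19) in replicate 1.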

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

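Of 267 alternative values of main results with a test, 238 kept their direction and their side of the threshold. Of 22 without a test, 15 stayed within 1.5 times (counts) or 1 SD of the replicates (ratios). That SD, used for named genes as well, comes from the same 2 values that serve as alternatives. Staying within it is therefore a weak check. With stricter peaks the X over autosome ratio of the replicated list fell to 1.02 and still counted as within it. Of the 22 lists, 15 stayed on their side of the threshold under every alternative run. The autosomal background, the requirement of overlap with both replicates, the alternatives for X and those for pairs of lists were chosen after seeing the data. Each replicate alone gave 3294 to 5318 marked genes, a promoter ratio of 7.42 to 10.5, 594 to 1758 long domains and an X over autosome ratio of 1.28 to 2.13, with replicate 2 at the end farther from the main value. A window at least 50% covered left 1643 marked genes, and joining gaps of 1 and 10 kb gave 386 and 1172 long domains. Endothelial, blood and microglia genes ranged from 1.501 to 2.43 in the replicates alone and passed the threshold with stricter peaks (2.47), the 500 bp window (2.54), the 50% window (3.65), overlap with both replicates (2.33), CpG-rich promoters (4.88) and autosomal genes (2.11), with adjusted p from 0.00721 to 0.233 over all alternatives. Only 3 of the 22 members had CpG-rich promoters, all 3 marked, so the value for that class says little about the whole list. Ribosomal protein genes ranged from 0.118 to 0.190 in the replicates alone and did not pass with stricter peaks (0.221), the 500 bp window (0.227), the 50% window (0.381) or overlap with both replicates (0.209). Cell cycle genes had a ratio of 0 in each replicate and in the same 4 settings and lost the threshold in these 4 and in replicate 1, as they did at any transcript start (0.227). Except at any transcript start, where 1 cell cycle gene was marked, these settings marked fewer genes in all, which lowers the count expected in both lists. Cyclin-dependent kinase inhibitors passed with the 2.5 kb window (3.06) and any transcript start (3.12). Under the 50% window, progenitor genes (2.14) and early neuron genes (2.33) no longer passed, and tissue-restricted genes (1.11) and Polycomb genes (0.921) changed direction without passing in either case. Imprinted genes lost the threshold within CpG-rich promoters (1.88), a class that held 13 of the 27 members. The cause of these changes was not tested for any list. Between pairs of lists, the ratio of marked shares in the replicates alone ranged from 1.39 to 2.00 for Wnt over Fgf and from 1.45 to 1.92 for Wnt over Bmp and Gdf ligands, and both pairs missed the threshold in replicate 2. It ranged from 0.962 to 1.04 for forebrain over midbrain factors and from 0.958 to 1.05 for Fgf over Bmp and Gdf ligands, without passing. Of 572 alternative values of named genes, 79 moved by more than 1 SD of the replicates. With the pooled list and with stricter peaks, 285 of 286 values moved by at most 1 SD. These settings are weak checks, since every replicated peak is in the pooled list and the stricter peaks are a subset of the replicated ones. With no olfactory or tissue-restricted gene in the CpG-rich class, these lists have no value there. The unknown depth limits every count.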

Other observations

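The scan of gene families, the tests of X with stricter peaks, with CpG-matched windows and with peaks that hold no repeat-masked base, and the comparison of peak strength for midbrain regulators without Hox genes were chosen after the result was seen, as were the genes named among the families and at the X domains. Families of genes that share a symbol stem were compared with all other genes, 273 families with at least 10 protein-coding members, and 28 were marked more often and 14 less often than other genes (Fisher's exact tests, Benjamini-Hochberg adjusted over the families). Of these, 26 and 14 passed in both replicates. All 14 Nkx homeobox genes were marked (adjusted exact p = 2.75e-10), with 7.59 kb of the 10 kb around the start in peaks on average. Of the 28 families, 14 had no member in a fixed list, and the 4 of these with the smallest p follow. Serotonin receptor genes were marked in 11 of 14 cases (5.04 times the share of other genes, adjusted exact p = 1.04e-05), among them Htr6 with 4.80 ± 0.936 kb (SD, n = 2) and Htr1a with 3.75 ± 0.522 kb, and the exceptions were Htr2b, Htr3a and Htr3b. Shisa genes, which include regulators of glutamate receptors, were marked in 9 of 11 cases (adjusted exact p = 6.09e-05) and adenylate cyclases in 8 of 10 (2.68e-04). Genes with the stem Cacna, which are part of the voltage-gated calcium channel subunits, were marked in 9 of 14 (adjusted exact p = 8.83e-04). The pore genes Cacna1a, Cacna1c and Cacna1d had no peak bases in either replicate. Serotonin receptor genes had 1.83 kb in peaks on average and genes with the stem Cacna 2.04 kb. Families that share members with the fixed lists also passed, among them genes with the stem Col, mostly collagens (21 of 45, adjusted exact p = 2.74e-05), and with the stem Slc, mostly transporters (92 of 371, 1.15e-04).

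Among families marked less often and without a member in a fixed list, the 4 with the smallest p had no marked member: 331 vomeronasal receptor genes (adjusted p = 4.62e-23), 67 histone genes (4.66e-04), 57 keratin-associated protein genes (0.00179) and 49 mitochondrial ribosomal protein genes (0.00540, Fisher's exact tests). Replicate 2 marked 2 of the keratin-associated genes, and each replicate marked 1 mitochondrial ribosomal gene. Zinc finger genes of the Zfp series were marked in 17 of 394 cases, 0.273 times the share of other genes (adjusted exact p = 1.13e-10), and in 20 and 40 cases in replicates 1 and 2. On X lay 5 of the 15 longest domains, 2 of them over Slc16a2, with spans of 85.4 and 74.5 kb and with 47.8 ± 18.8 and 37.8 ± 18.0 kb (SD, n = 2) in peaks. Their near ends were 195 and 284 kb from the start of Xist, the RNA that silences the inactive X, and those of the other 3 were 3871, 48553 and 48670 kb from it.

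X coverage stood above the CpG trend of the autosomes, at 4.57 times the trend in replicate 1 and 6.45 times in replicate 2, with the trend extrapolated to the lower CpG density of X. In windows of 10 kb without a protein-coding start and matched for CpG count, X had 4.87 times the covered share of autosomes in replicate 1 and 6.78 times in replicate 2, while single autosomes ranged up to 1.81 and 1.66 times. In windows with a protein-coding start the ratio was 1.22 in replicate 1, inside the range of single autosomes (up to 1.33), and 1.95 in replicate 2 (up to 1.23). With stricter peaks these windows gave 1.07 in replicate 1 (up to 1.35) and 1.58 in replicate 2 (up to 1.25). With peaks that hold no repeat-masked base they gave 2.37 in replicate 1 and 2.81 in replicate 2, with single autosomes up to 1.23 in both. The tables argue against repeat-masked sequence as the whole source, since peaks without a repeat-masked base gave a ratio of at least 6.34 in both replicates for windows without a start. These peaks were a small part of the signal. They covered 0.195% of such windows on X in replicate 1, against 0.719% for all peaks, and 0.570% against 3.17% in replicate 2. Repeated sequence outside the mask was not tested. Weak calls as the whole source are argued against, since stricter peaks gave at least 3.98 times the trend in both replicates. An inactive X may contribute and cannot be told apart here: 8 genes known to escape inactivation were covered over 5.53% of gene body and 10 kb flanks (median 5.74%), against 5.30% (median 0.758%) for 221 CpG-rich X genes outside that set (difference of means 0.228 percentage points, two-sided permutation test, p = 0.947), and 8 genes are too few to decide.

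Replicate 2 gained more on X than elsewhere. Its covered bases were 4.27 times those of replicate 1 on X, against a range of 2.15 to 2.82 times over the 19 autosomes. Weaker X peaks entering with the longer list are argued against as the whole source, since among the 34300 strongest peaks of replicate 2 the X share was 18.0% (exact 95% interval 17.6 to 18.4%) against 13.2% (12.8 to 13.5%) in replicate 1, intervals that cover counting error only. A different share of female embryos in the 2 pools could raise the X of one pool and stays open, untested, since the proportions in the mixed pools are not given in the sources used here.

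Midbrain and isthmus regulators were marked in 27 of 29 cases, a share that did not differ detectably from that of forebrain regional factors, 26 of 28 (adjusted p = 1.00, Fisher's exact test). Membership of the CpG-rich class does not account for all of the enrichment of this list, since within CpG-rich promoters it kept a ratio of 4.42 to other genes (adjusted p = 1.95e-10, Fisher's exact test). CpG content was not matched within that class, so a part played by it stays open. That many of these genes are active in part of the cells, and silent and marked in the rest, cannot be told apart here. In a comparison of peak strength, genes without a peak entered at the floor of the scale, so that absence and strength are mixed. The strongest peak within 5 kb of the start had a −log10 p that differed by −0.970 on average over the replicates between midbrain regulators and forebrain and mesoderm factors (two-sided permutation p = 0.874 in replicate 1 and 0.657 in replicate 2, values shared on a chromosome counted once). With Hox genes included it was −5.88 (permutation p = 0.0291) in replicate 1 and −11.0 (p = 0.00311) in replicate 2, and −4.41 (p = 0.108) and −6.31 (p = 0.0679) when shared values were counted once.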
